A study of Mus musculus with 11 samples.

How the data were processed

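Retinas of mice at postnatal day 21 were profiled by sequencing of RNA depleted of polyadenylated transcripts, in 5 wild-type libraries and 6 libraries of mice lacking Nrl, the transcription factor that directs photoreceptor precursors to the rod fate. Per the labels' protocols, reads were single-end, stranded and 50 bp long. The labels number the replicates without naming animals, so p-values measure the spread between these libraries, which may in part be technical.

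The deposited table lists non-coding features with one signal column per library. These values are DESeq2-normalised read counts made by the authors, per the file headers and the table's name, which also gives the mm10 build. The submitters' processing notes name TopHat2 2.0.10, Cufflinks 2.2.1, Cuffdiff and the builds mm9 and mm10, with no role or order. The assembler behind the MSTRG feature names, the counting tool, and whether counting used strand are not given in the sources used here. The deposited log2 fold change and its standard error, the deposited Wald score and the deposited p-value and adjusted p-value are the authors' own comparison, per the file headers. The deposited score has the sign opposite to the deposited log2 fold change in 100% of features, so signs were taken from the fold change and the group means. No filter is stated in the sources used here, but the lowest mean in the table was 2.00 normalised counts. The table also gives, for each feature, a chromosomal domain and the mRNAs listed as higher or lower within that domain; how those mRNA lists and domains were made is not given in the sources used here.

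The table has 36180 lines and 36097 unique features, 83 of which have 2 lines because they lie in 2 domains; each was used 1 time. Of these features, 35942 carry an assembled-transcript name and 155 an Ensembl name. Their median length was 235 bp. Positions are those of the table, written counting from 1. Features were placed by overlap with the GENCODE M21 annotation of the same build: on the strand of a gene, opposite to a gene (antisense), or intergenic. Because strand use in counting is not stated, reads of a feature and of a gene on the opposite strand cannot be told apart with certainty.

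Every value of a library was a whole multiple of that library's smallest value above 0. With a tolerance of 0.001, 100% of values came out whole. The reads so counted ranged from 3238184 to 4150460 per wild-type library and from 3374221 to 4876429 per knockout library. They count reads in the listed features, not whole libraries. A count of 0 allows up to 3 reads, which is 2.28 to 4.11 normalised counts depending on the library. Intervals and floors cover counting error only, since no molecular identifiers were used here. In the simulation described next, at this depth and replication, limma recovered most 4-fold changes and few 1.5-fold changes.

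The main test was limma 3.58.1 (lmFit, then eBayes with trend and robust) in R 4.3.3, on log2(normalised count + 1), two-sided, with group as the only term and Benjamini-Hochberg adjustment; features with a mean of at least 5 over the 11 libraries were tested, and an adjusted p below 0.05 was a call. A log2 difference on this scale understates changes of low features. The fit was tested on simulated data: 21395 features with the real means and library sizes, a negative binomial dispersion of 0.05, and 200 changed features. limma recovered 2 of 70 features changed 1.5-fold, 27 of 64 changed 2-fold and 61 of 66 changed 4-fold, with 2 false calls and 0 of the wrong sign. On 9 of the simulated libraries edgeR recovered 2, 18 and 58 of these and DESeq2 1, 16 and 52, with 0 and 1 false calls. The simulated share of changed features was far below the 28.1% called in the data, which makes the adjusted threshold stricter in the simulation. It also gave all features 1 dispersion and had no variation shared by the features of a library. Recovery in the data may therefore differ. For the deposited data, count tests with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the whole reads of 9 libraries, 4 wild-type and 5 knockout. Wild-type 5 and knockout 2 were left out of them by a rule against libraries where 1 read is worth close to 1 normalised count (1.0087 and 1.0097). Their values too came out 100% whole, so leaving them out was a choice of procedure. edgeR called 5733 features and DESeq2 5468, against 5640 by limma on the same 9 libraries. DESeq2 gave no adjusted p for 2 features.

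Genes were grouped into 18 lists written before the data were examined: rod photoreceptor, cone photoreceptor, photoreceptor transcription factors, bipolar cell, Müller glia, glial and stress response, amacrine cell, retinal ganglion cell, horizontal cell, retinal pigment epithelium, vascular and pericyte, microglia and immune, erythrocyte, lens, retinal long non-coding RNAs, photoreceptor microRNA loci, polymerase III and small nuclear RNA, and replication-dependent histones. A feature belonged to a list when it overlapped a member gene on either strand. Intergenic features whose nearest coding transcription start, within 100 kb, was that of a member were counted apart. Distances to a start were measured from the middle of the feature. Features of the microglia and immune list are not reported here. Lists of at least 3 features were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry. Features named in the text followed a rule also fixed beforehand: the feature at Nrl; among called features with a mean of at least 20 and no overlap between the groups, the 12 largest rises and 12 largest falls; per list, up to 4 called features with the smallest adjusted p, and for the rod, cone and transcription factor lists up to 3 uncalled features of the highest mean; and the 3 features of the highest mean. Where several were of 1 gene, the one with the highest mean is named.

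The comparison of domains was added after the table's columns were seen. Features listed in 2 domains were left out of it, shares carry 95% Wilson intervals, and the domain kinds were permuted 100000 times over domains with a two-sided test. Alternatives fixed beforehand were other scalings (TMM, equal totals, quantile), pseudocounts of 0.5 and 5, no filter, a mean of at least 20, the count tests, sample weights, a replicate block, a 2-fold requirement, leaving out each library in turn, and, for the lists, other set tests and intergenic members within 100 or 20 kb. Chosen after seeing the data were limma on 9 libraries, the second principal component as a covariate, features with no gene on their own strand, and the 3 alternatives for domains. Of the libraries' pairs within a group, none held the same library: chi-square per feature was 2.29 to 15.2, where sampling noise alone gives about 1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the domain tests, exact permutation tests and figures.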

Results

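The labels set 1 question for these libraries: which non-coding transcripts of the adult mouse retina differ when Nrl is missing. Nrl is the transcription factor that directs photoreceptor precursors to the rod fate, and photoreceptors of the knockout retina are known to resemble cones. RNA depleted of polyadenylated transcripts was sequenced from 5 wild-type and 6 Nrl knockout retina libraries at postnatal day 21. The listed features held 3238184 to 4150460 reads per wild-type library and 3374221 to 4876429 per knockout library. The 10 most abundant features took 34.8% to 46.4% of these reads in wild-type and 33.9% to 53.5% in knockout. Knockout 2, the library with 4876429, and wild-type 5 were left out of the count tests by a rule, though their values too came out whole. Pairs of libraries correlated at 0.880 to 0.941 within wild-type, 0.890 to 0.941 within knockout and 0.672 to 0.745 between the groups, across the log2 values of the tested features.

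At the Nrl locus itself, the feature placed on the strand opposite to Nrl had almost no reads in the knockout. The feature MSTRG.28375, on chromosome 14 from 55521461 to 55522460 (mm10, plus strand), lies inside the Nrl gene (55518978 to 55524981, minus strand), with 100% of its length over Nrl exons. It held 42.1 ± 9.42 normalised counts in wild-type (SD, n = 5) and 0.126 ± 0.310 in knockout (SD, n = 6), where 1 library held 0.758 and the other 5 held 0. In the 9 libraries of the count tests this was 172 reads against 1, a ratio of 245 with an exact 95% interval of 43.3 to 9718 for counting error. The log2 difference was -5.27 (SE 0.37, limma adjusted p = 7.43e-12), and an exact two-sided permutation test gave p = 0.00216, 1 of 462 splits. In the authors' deposited table the same feature has a log2 fold change of -7.47 (SE 0.87, adjusted p = 5.06e-16). The libraries thus matched their labels at this feature, although the part of Nrl changed in the knockout allele is not given in the sources used here. Whether the reads of MSTRG.28375 came from the opposite strand or from Nrl mRNA cannot be told, because strand use in counting is not given either.

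The 2 neighbouring features, chosen after their values were seen except for MSTRG.28378, went opposite ways. MSTRG.28377 (chromosome 14, 55525868 to 55526801, minus strand) has its middle 1353 bp from the Nrl start. It dropped from 117 ± 49.0 (SD, n = 5) to 6.08 ± 3.24 normalised counts (SD, n = 6), a log2 difference of -4.11. MSTRG.28378 (55528827 to 55532520, plus strand, antisense to the predicted gene Gm10876) went from 2.64 ± 1.74 (SD, n = 5) to 408 ± 42.9 (SD, n = 6), a log2 difference of 6.92. Of the 236 features tested within 10 Mb of Nrl, 118 were called, against 27.9% of the features elsewhere.

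**Figure D1:**
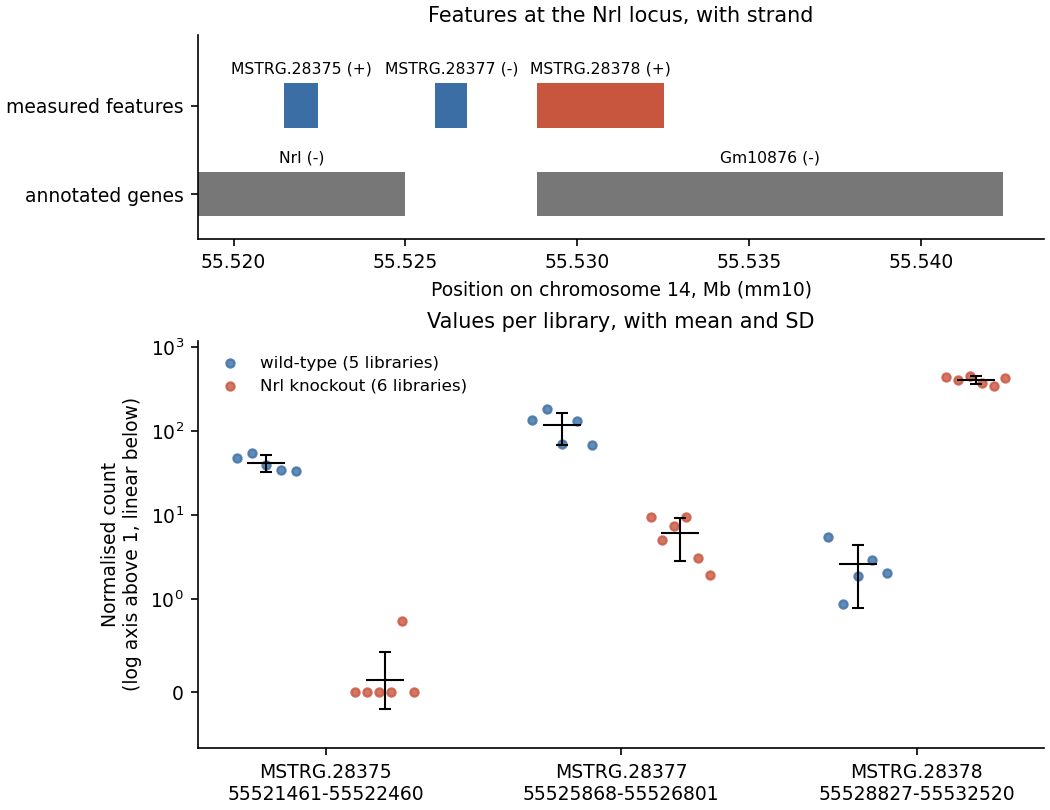
The upper panel maps annotated genes and the 3 measured features at the Nrl locus by position on chromosome 14 (Mb, mm10), and the lower panel gives each library's normalised count (log axis above 1, linear below) with group mean and SD. All 5 wild-type libraries lie above all 6 knockout libraries at MSTRG.28375 and MSTRG.28377, and below them at MSTRG.28378.

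Of the 21395 non-coding features tested across the retina, 3327 were higher and 2695 lower in knockout, together 28.1%. At least 2-fold differences were seen for 2746 of the higher and 2040 of the lower features, and at least 16-fold differences for 144 and 346. The called features lay in 1864 higher and 1719 lower regions when features within 10000 bp of each other were joined. Intergenic features made up 1765 of the higher and 1172 of the lower calls, out of 10797 tested. Features antisense to coding genes made up 1024 and 1046 calls out of 6265, and those in annotated non-coding genes 350 and 336 out of 2868. Features antisense to non-coding genes made up 145 and 115 out of 791, and features on the strand of a coding gene 43 and 26 out of 674.

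**Figure D2:**
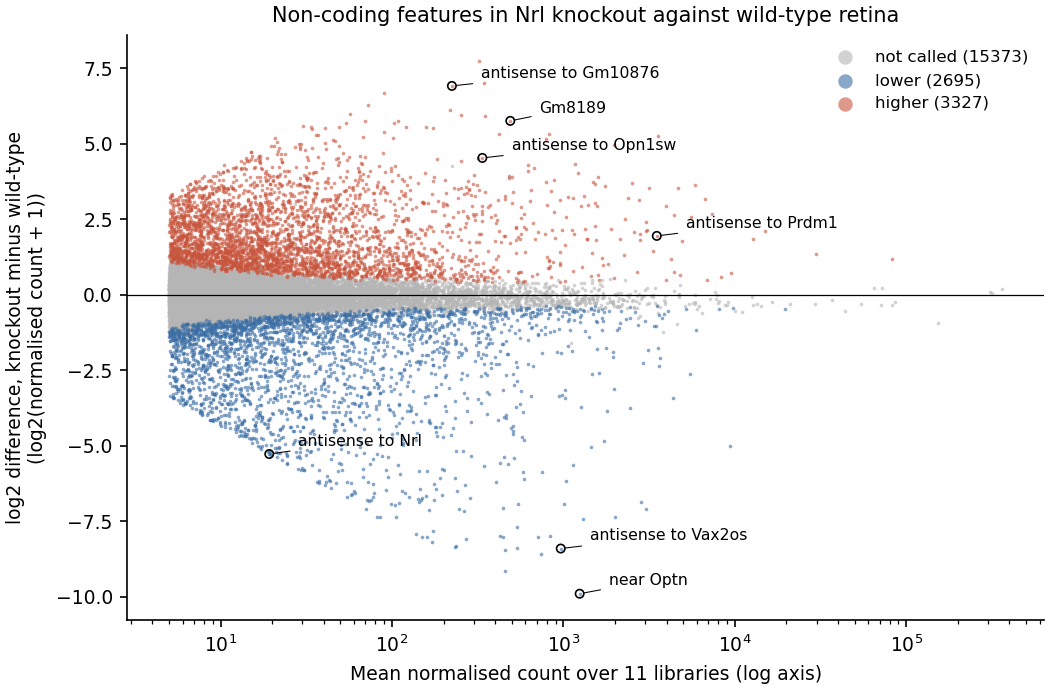
Each point is 1 of 21395 tested features, by its mean normalised count over 11 libraries (log axis) and its log2 difference between knockout and wild-type on the scale of log2(normalised count + 1); circled features are named. Called features, 3327 higher and 2695 lower, lie at both low and high counts, though the 3 features of the highest mean were not called. The slanted outer edge at low counts comes from the pseudocount.

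The largest falls, 12 features of which 11 are named because 2 lie at Gm11342, left a few normalised counts or less in knockout. The intergenic MSTRG.46971 (chromosome 2, 5075108 to 5083538, minus strand) fell from 2734 ± 622 (SD, n = 5) to 2.198 ± 1.48 (SD, n = 6), a log2 difference of -9.89. Its neighbour MSTRG.46973 (5083595 to 5083845, same strand) fell from 1003 ± 228 to 0.769 ± 0.392, a log2 difference of -9.16. The nearest coding start for both is that of Optn, which encodes the autophagy receptor optineurin. This start lies 15272 and 19669 bp from the middle of each feature. MSTRG.23521 (chromosome 13, 24349295 to 24361998), in the annotated non-coding gene Gm11342 and antisense to Cmah, fell from 1631 ± 413 to 3.51 ± 1.76. MSTRG.74898 (chromosome 6, 83698281 to 83701902), antisense to the retinal non-coding RNA Vax2os, fell from 2117 ± 399 to 5.32 ± 1.36, a log2 difference of -8.40. The other falls of this group included MSTRG.27654 in Gm49024 (-8.44), MSTRG.16172 near Ypel2 (-8.40) and MSTRG.98260 on chromosome X (-8.34). Another was MSTRG.80767 (-8.30), with its middle 1068 bp from the start of the tight-junction gene Tjp1. MSTRG.23567 on chromosome 13 (-8.17), MSTRG.65738 antisense to Gnb1 (-8.10) and MSTRG.68455 antisense to Cnga1 (-8.03) completed the group. In knockout MSTRG.46973, MSTRG.98260, MSTRG.80767, MSTRG.23567 and MSTRG.68455 averaged 0.769, 0.643, 0.761, 0.336 and 0.289 normalised counts, so the size of their log2 differences depends on the pseudocount.

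The largest rises, 12 features of which 10 are named because 3 lie at Def8, mostly started from a few normalised counts in wild-type. The intergenic MSTRG.25914 (chromosome 13, 97835280 to 97845656, minus strand) went from 1.99 ± 1.55 (SD, n = 5) to 588 ± 86.3 (SD, n = 6), a log2 difference of 7.74. The adjacent MSTRG.25908 (97779286 to 97833490, same strand), in the predicted non-coding gene Gm41031, went from 4.35 ± 3.37 to 624 ± 151, a log2 difference of 7.01. Next were MSTRG.28378 near Nrl (6.92), MSTRG.89153 antisense to Def8 on chromosome 8 (6.68), MSTRG.21903 antisense to Catsperb on chromosome 12 (6.13) and its neighbour MSTRG.21904 (5.93). MSTRG.44704 (5.98) and MSTRG.44710 (5.76) lie near each other on chromosome 19, the latter in Gm8189, where it went from 15.2 ± 2.02 to 885 ± 144. MSTRG.21499 near Irf2bpl (5.95) and MSTRG.3392 on chromosome 1 (5.75) completed the group. In wild-type MSTRG.89153 held 2.78 normalised counts in 1 library and 0 in the other 4, and MSTRG.44704 averaged 0.656, so their log2 differences too depend on the pseudocount.

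These counts come from limma, with Benjamini-Hochberg adjustment over all tested features; the limma adjusted p was 3.57e-21 to 5.75e-17 for the named falls and 5.32e-19 to 1.49e-11 for the named rises. Over all tested features the groups did not overlap in 20.2%, against 0.433% by chance, and 4223 of the 6022 calls were among them. The authors' deposited table gives 6990 features an adjusted p below 0.05, 3930 higher and 3060 lower, without the limit on the mean used here. Of these, 5574 were tested here, and 5525 of the 6022 limma calls are among them. Requiring a mean of at least 20 left 8266 features tested, with 1722 higher and 1628 lower.

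Features overlapping rod genes mostly fell. The list held 54 tested features at 22 rod genes, all on the strand opposite to the gene: 36 fell, 4 rose and 14 were not called, with a median log2 difference of -2.21. Adjusted over the list alone, 38 fell and 4 rose, the feature at Nrl among those that fell. MSTRG.68455 (chromosome 5, 72612161 to 72612279) overlaps an exon of Cnga1, the rod cyclic nucleotide-gated channel, and fell from 328 ± 87.1 (SD, n = 5) to 0.289 ± 0.453 normalised counts (SD, n = 6). MSTRG.65738 (chromosome 4, 155493061 to 155494998), inside an intron of Gnb1, the beta subunit of rod transducin, fell from 597 ± 133 to 1.34 ± 1.05; of 5 features at Gnb1, 4 fell. MSTRG.92026 (chromosome 9, 64927950 to 64928709), over an exon of the rod exchanger gene Slc24a1, fell from 425 ± 127 to 3.39 ± 1.27, a log2 difference of -6.62. Reads of a host gene cannot be told from reads of a feature on its other strand if counting ignored strand, which is not given in the sources used here, so the values of antisense features are uncertain to that extent.

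The 4 rod-list features that rose, named after their values were seen, were at 2 genes. At Pde6b, which encodes a subunit of the rod phosphodiesterase, the log2 differences were 1.28 and 3.10, from means of 2.501 and 0.186 normalised counts in wild-type. At Sag, the rod arrestin gene, they were 0.68 and 1.60, while a further Sag feature fell, by 1.58 on the log2 scale. Uncalled features of the highest mean were MSTRG.15161 at Aipl1 (403 ± 131 in wild-type and 284 ± 97.2 in knockout, log2 difference -0.51, adjusted p = 0.0982 in limma), MSTRG.38439 at Tulp1 (31.5 ± 10.6 and 31.1 ± 12.9) and MSTRG.21444 at Esrrb (32.9 ± 8.77 and 23.2 ± 12.4). The Aipl1 feature was called by edgeR (adjusted p = 0.0290) and DESeq2 (adjusted p = 0.0460) and in limma without wild-type 5 (adjusted p = 0.0275) or knockout 1 (adjusted p = 0.0289). camera gave an adjusted p of 2.86e-17 for the rod list in the lower direction, which stayed below the threshold with an estimated correlation (adjusted p = 0.0263). Of 25 intergenic features near rod genes 10 fell and 7 rose, with a median log2 difference of -0.16; with these counted in, the adjusted p with an estimated correlation was 0.0657. Among overlapping features with a mean of at least 20, 21 fell.

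Features overlapping cone genes mostly rose. Of 37 tested features at 14 genes, all antisense, 25 rose, 3 fell and 9 were not called, with a median log2 difference of 2.09. Adjusted over the list alone the counts were the same, 25 and 3. MSTRG.72794 (chromosome 6, 29388335 to 29390593, plus strand), which touches an exon of Opn1sw, the short-wavelength cone opsin gene, with 94.1% of its length beyond the gene, rose from 24.8 ± 8.14 (SD, n = 5) to 596 ± 172 normalised counts (SD, n = 6), a 24.0-fold ratio of the means. MSTRG.60259 (chromosome 4, 19445645 to 19445769), in an intron of the cone channel gene Cngb3, rose from 4.69 ± 2.01 to 63.0 ± 16.9, and all 4 Cngb3 features rose. MSTRG.45842 (chromosome 19, 38142415 to 38142607), in an intron of Pde6c, the cone phosphodiesterase gene, rose from 7.92 ± 2.89 to 100.4 ± 22.9, a log2 difference of 3.55. The 3 cone-list features that fell were named after their values were seen. Among them, 2 of the 7 features at Pde6c had log2 differences of -0.70 and -0.69, and 1 feature at Guca1a had a log2 difference of -3.11; Guca1a encodes a guanylate cyclase activator used by photoreceptors. Uncalled features were MSTRG.45850 at Pde6c (47.0 ± 8.64 and 58.3 ± 13.6) and MSTRG.413 at Kcnb2 (45.5 ± 16.6 and 42.7 ± 13.3). camera gave an adjusted p of 2.16e-08 for the cone list in the higher direction, and the adjusted p was 0.00811 with an estimated correlation. Among features with a mean of at least 20, 13 rose.

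Features at transcription factors of photoreceptors changed in both directions, 14 up and 14 down of 41 at 13 genes, with 13 not called and the same 14 and 14 adjusted over the list alone. Those at Esrrb, Nrl and Samd7 are also counted in the rod list, and those at Thrb and Rxrg in the cone list. They are not separate evidence. MSTRG.21447 (chromosome 12, 86506765 to 86507755), antisense to Esrrb, a nuclear receptor of rods, fell from 360 ± 106 (SD, n = 5) to 2.04 ± 1.77 (SD, n = 6), and 6 of 7 Esrrb features fell. MSTRG.6882 (chromosome 1, 188026736 to 188030216), antisense to the related receptor gene Esrrg, rose from 35.8 ± 6.00 to 416 ± 82.0, and 4 of 8 Esrrg features rose. MSTRG.8736 (chromosome 10, 44471744 to 44487484), antisense to Prdm1, a repressor that guards photoreceptor against bipolar fate, rose from 1352 ± 48.8 to 5303 ± 877, a log2 difference of 1.96. Uncalled were MSTRG.57050 at Mef2d (253 ± 62.0 and 287 ± 89.0), MSTRG.6872 at Esrrg (176 ± 18.9 and 165 ± 22.1) and MSTRG.8734 at Prdm1 (74.9 ± 26.2 and 111 ± 49.6), which had an adjusted p of 0.165 in limma and of 0.0478 without wild-type 1. The list's median log2 difference was 0.16 and its mean -0.25, and camera gave an adjusted p of 0.985 in the higher direction, the mean's sign being the opposite (adjusted p = 0.993 with an estimated correlation).

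**Figure D3:**
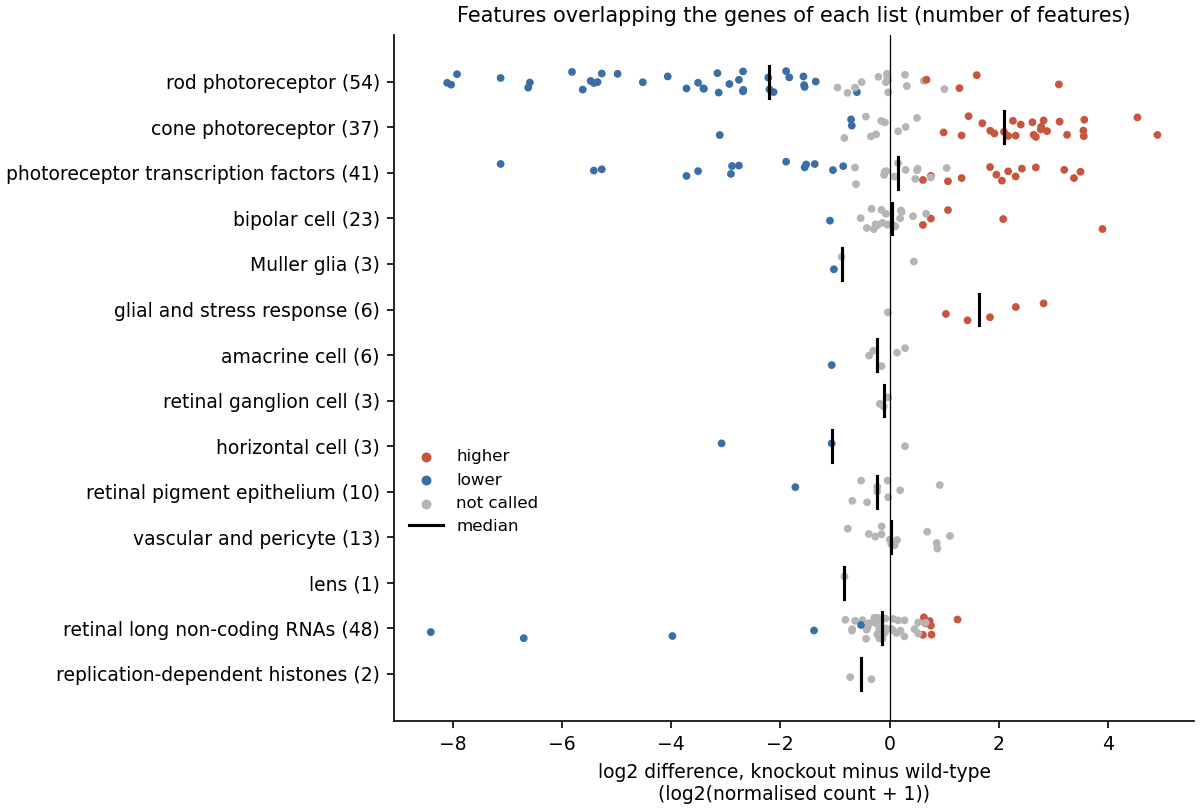
Each point is a tested feature overlapping a gene of the list named on the left (number of features in parentheses), by its log2 difference between knockout and wild-type on the scale of log2(normalised count + 1); vertical bars are medians. Rod features have a median of -2.21 and cone features one of 2.09.

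Features overlapping marker genes of other retinal cells were fewer. Of 23 bipolar features at 11 genes, 5 rose, at 3 genes, and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.577). MSTRG.77945 (chromosome 7, 13406691 to 13408350), antisense to the calcium-binding protein gene Cabp5, rose from 14.2 ± 5.96 (SD, n = 5) to 222 ± 65.6 (SD, n = 6). MSTRG.5399, antisense to Lhx4, a homeobox gene of bipolar and cone cells, rose from 15.9 ± 5.51 to 69.8 ± 15.98, and MSTRG.27970, on the strand of Otx2, a photoreceptor and bipolar regulator, had a log2 difference of 0.61 (limma adjusted p = 0.00781), with values of the groups overlapping. All 3 features at Otx2 rose and made up most of the bipolar rises, and Otx2 is also on the transcription factor list. Otx2 lies within 10 Mb of Nrl, where 118 of 236 features were called. MSTRG.17527, 1 of 7 features at the rod bipolar marker Prkca, had a log2 difference of -1.09.

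The glial and stress response list, which holds genes induced in injured retina, had 6 features at 5 genes, of which 5 rose, also 5 when adjusted over the list alone, and 1 was not called. MSTRG.18014, antisense to the cytokine signalling inhibitor gene Socs3 with 63.2% of its length beyond the gene, rose from 9.30 ± 4.88 (SD, n = 5) to 65.5 ± 14.7 (SD, n = 6); Socs3 is also on the cone list. MSTRG.34675, on the strand of the acute-phase regulator Cebpd, rose from 228 ± 48.8 to 831 ± 243. MSTRG.55708 antisense to the growth factor gene Fgf2 and MSTRG.78354 antisense to Bcl3 had log2 differences of 2.31 and 1.03. camera gave an adjusted p of 0.00209, a call that was lost with an estimated correlation (adjusted p = 0.128).

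In Müller glia, 1 of 3 features fell (2 adjusted over the list alone): MSTRG.54875 in an intron of the carbonic anhydrase gene Car2, 10.5 ± 2.13 against 5.05 ± 2.48, with adjusted p = 0.0342 in limma. It was not called by DESeq2 (adjusted p = 0.0577), nor in limma without wild-type 2, wild-type 3, wild-type 5, knockout 5 or knockout 6, where the adjusted p was 0.0907, 0.0614, 0.0758, 0.0879 and 0.0579. Of 6 amacrine features 1 fell, and of 3 horizontal cell features 2 fell, with the same counts adjusted over each list alone: MSTRG.6946 at Prox1 (-1.06), a gene on both lists, and MSTRG.31990 at Ndrg1 (-3.07). limma called 0 of the 3 ganglion cell features and 0 of the 13 vascular features, over all features and adjusted over the list alone. At unadjusted p under 0.05 there were 0 and 1, and edgeR and DESeq2 each called 0 and 1 of them. Of 10 features at Trpm3, the one pigment epithelium gene measured, MSTRG.45256 had a log2 difference of -1.72, also the 1 call adjusted over the list alone. The 1 lens feature, at Bfsp2 (log2 difference -0.84), was not called by limma over all features; it was lower adjusted over the list alone, and in edgeR and DESeq2. The camera adjusted p was 0.615 for the Müller, amacrine and pigment epithelium lists, 0.268 for the horizontal and 0.878 for the ganglion cell and vascular lists.

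Of the retinal long non-coding RNAs, 48 features at 9 genes were measured, of which 7 rose and 5 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.577). All 3 features at Vax2os fell, with a log2 difference of -8.40 at MSTRG.74898. MSTRG.27978, 1 of 13 features at Otx2os1, went from 3149 ± 440 (SD, n = 5) to 5451 ± 1345 (SD, n = 6), a log2 difference of 0.77; it too lies within 10 Mb of Nrl. limma called 0 of the 2 features at replication-dependent histone genes, also adjusted over the list alone; 0 had an unadjusted p under 0.05, and edgeR and DESeq2 called 0. There were 0 tested features at the erythrocyte genes, the photoreceptor microRNA loci and the polymerase III and small nuclear RNA genes. The 3 features of the highest mean were MSTRG.7707 (333883 ± 93308 and 387159 ± 127177 normalised counts, with 498086 in wild-type 1), MSTRG.47665 (309776 ± 82392 and 326314 ± 95828) and MSTRG.39223 in Gm26917 and Gm42418 (300298 ± 114268 and 314788 ± 83661). limma, edgeR and DESeq2 called 0 of the 3, and 0 had an unadjusted p under 0.05. MSTRG.39223 overlaps loci that share sequence with ribosomal RNA, and its count is uncertain to that extent.

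Non-coding features more often fell in chromosomal domains with listed lower mRNAs, and more often rose in domains with listed higher mRNAs, a comparison added after the columns were seen. In the 348 domains for which the deposited table lists only lower mRNAs, 25.6% of 2983 features fell (95% Wilson interval 24.1 to 27.2) and 9.05% rose (8.07 to 10.1). In the 585 domains that list only higher mRNAs, 29.8% of 5411 features rose (28.6 to 31.1) and 7.97% fell (7.27 to 8.72). In the 239 domains with both, 16.7% of 3002 features rose and 14.5% fell, and in the 1493 domains with neither, 9.35% of 9938 rose and 10.6% fell. Among the 858 lower and 1453 higher mRNAs that the deposited table lists, 26 of the 34 genes of the rod list are lower and 0 higher. Of the 27 cone genes 20 are listed as higher and 1 as lower, and 16 of 20 glial and stress genes and 13 of 16 microglial genes are listed as higher.

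The share that fell differed by 17.7 percentage points between domains with only lower and only higher mRNAs, and the share that rose by 20.8 points. Permuting the kind of domain 100000 times gave p = 1e-05 for each (two-sided), the smallest these permutations can give. The Wilson intervals treat features as independent, which neighbours within a domain are not. How the mRNA lists were made is not given in the sources used here, and if they come from retinas of the same study they are not independent of these libraries.

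**Figure D4:**
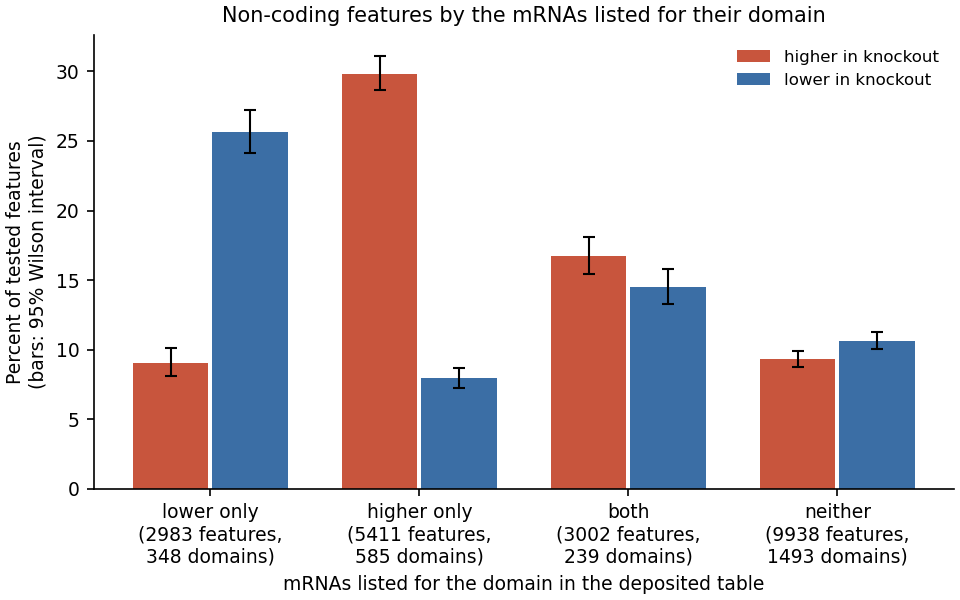
Bars give the percent of tested features that were higher or lower in knockout, by the mRNAs that the deposited table lists for their domain, with 95% Wilson intervals. In domains listing only lower mRNAs 25.6% of features fell, and in those listing only higher mRNAs 29.8% rose.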

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

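The tests of a strain interval, the count of features mostly over exons and the length outside host genes without MSTRG.72794 were tests chosen only after the result was seen.

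Of 110 groups of 5 or 6 libraries, 106 for the 53 named features and 4 for total reads and the share of the 10 most abundant features, 9 held a library far from the others, where chance alone gives about 1 in 20 groups, or 5.5. In knockout 5, MSTRG.28375 at Nrl held 0.758 normalised counts and the other knockout libraries 0. In the same library MSTRG.25908 held 341, against 587 to 750 in the others. MSTRG.5399 at Lhx4 held 39.4 there, against 68.1 to 83.0. In knockout 4, MSTRG.46973 held 0, against 0.758 to 1.04. In wild-type 1, MSTRG.68455 at Cnga1 held 481, against 276 to 312 in the other wild-type libraries. MSTRG.60259 at Cngb3 held 1.37 there, against 4.70 to 6.50. MSTRG.7707 held 498086 there, against 269979 to 313933. In wild-type 3, MSTRG.89153 held 2.78 and the others 0. In wild-type 2, MSTRG.21903 held 0.941, against 5.04 to 6.77.

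A chance split of the libraries is argued against as the source of both counts of called features, as far as 100 of the 462 possible splits can show. Of 100 splits of the 11 libraries into 5 and 6, the real one included, 1 gave as many features higher, with 3327 in the real split and 1847 in the highest other. Likewise 1 of the 100 gave as many features lower, with 2695 and 2290. The 2 other splits with the most calls each set 5 knockout libraries against the remaining 6.

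Called features on the strand opposite to rod and cone genes mostly fell at rod genes and rose at cone genes, and technically this could come from reads of the host gene landing on the wrong strand. If the source were spliced host mRNA, most of their length would lie over host exons; the median share of the 68 called features was 0% (bootstrap 95% interval 0 to 16.5), and 36 had no exonic base, which argues against spliced mRNA as the whole source. For the 18 features with over 50% of their length over exons it stays open, because host mRNA was not measured here. Most of these are at rod genes, among them MSTRG.28375 at Nrl (100%), MSTRG.68455 at Cnga1 (93.3%) and MSTRG.92026 at Slc24a1 (98.9%). MSTRG.65738 at Gnb1 has 0%. The pooled median thus speaks less to the falls at rod genes than to the rises at cone genes. The bootstrap treats features of the same gene as independent, which they may not be. Unspliced host RNA stays open too: 65 of the 68 features lay wholly inside the host gene, as it would need, and 6.84% of the summed length lay outside, between the values set for and against it. That length came from MSTRG.72794, MSTRG.45852 and MSTRG.18014, and without MSTRG.72794 at Opn1sw it was 3.15%, below the value of 5% set for it. A difference between rods and cones in true antisense transcription is the biological alternative that the groups give, and it was not tested apart from these.

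Called features of 1 direction lay in 32 runs of at least 10 neighbours, 24 higher and 8 lower, such as 55 higher features on chromosome 12 from 6138495 to 6966795 and 38 lower features on chromosome 1 from 70652633 to 70918375, which holds Spag16 and Vwc2l. A strain interval linked to the Nrl mutation on chromosome 14 cannot account for most of them, since 1 of the 32 runs lay within 10 Mb of Nrl. Pieces of a long transcript counted as separate features could account for runs on a single strand: in 68.8% of runs at least 90% of features were on 1 strand (exact 95% interval 50.0 to 83.9), too close to the value set in advance to decide. In 10 runs over 10% of the features lay on each strand, which a single transcript would not give. A regional change of transcription between the genotypes stays open, as untested.

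Within 10 Mb of Nrl 118 of 236 tested features were called, 50 higher and 68 lower, against 27.9% elsewhere. A strain interval linked to the Nrl mutation, carried along from the strain in which the allele was made, may contribute: 1 of 106 windows of 20 Mb on other chromosomes had as high a share called, the highest having 52.8% and the median window 29.1%. The strains of the mice are not given in the sources used here, and regulation of this region by Nrl or by photoreceptor identity stays open, as untested.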

How the results depend on the processing

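The fit on 9 libraries by limma, the second principal component as a covariate, the features with no gene on their own strand, and the domain comparison with its 3 alternatives were tests chosen only after the result was seen.

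None of the 6022 calls was reversed in 25 alternative fits, 11 of them leaving out a library. With a mean of at least 20 required, 1722 features were higher and 1628 lower, with 21 rod features lower and 13 cone features higher, because 8266 features were tested; MSTRG.28375 at Nrl was not among them. Counting intergenic features within 100 kb raised the calls in the other lists to 111 from 50, by construction. Otherwise 2746 to 4314 features were higher and 2040 to 3566 lower, with 35 to 46 rod features lower, 24 to 35 cone features higher and 35 to 75 calls in the other lists. Leaving out each library gave 3115 to 3456 higher and 2366 to 2785 lower, with 5379 to 5653 of the 6022 calls shared. The log2 difference at Nrl was -7.48 to -3.18 over the alternatives (limma, edgeR or DESeq2 adjusted p 1.25e-15 to 6.41e-10) and -5.40 to -5.16 without each library. Under the 3 other scalings 54.4% to 56.0% of calls were higher, and the median of all features was -0.03 to -0.02. The domain differences were 13.02 to 19.3 points for lower and 16.6 to 22.5 for higher features.

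Values of uncalled named features near 0 changed sign, with adjusted p of 0.469 or more; the cause was not tested. With quantile normalisation MSTRG.6872 was at 0.011 and MSTRG.7707 at -0.012. With edgeR on 9 libraries MSTRG.413 was at 0.29, MSTRG.47665 at -0.076 and MSTRG.39223 at -0.053. With DESeq2 these were at 0.26, -0.12 and -0.10 and MSTRG.57050 at -0.033; with limma on the same 9 libraries they were at 0.27, -0.12, -0.072 and -0.038. Leaving out each library moved MSTRG.38439 over -0.23 to 0.12, MSTRG.413 over -0.25 to 0.10 and MSTRG.47665 over -0.044 to 0.20. Of the other values of the 53 named features, 1282 kept their side of the threshold, 9 gained a call, at Aipl1 and Prdm1, and 8 lost it: 6 at Car2, and 1 each at Otx2 and Otx2os1, whose changes are under 2-fold. Of the list counts 685 stayed within 1.5 times and 71 did not. Without wild-type 1, knockout 2, knockout 5 or knockout 6 limma called 1 vascular feature, and without wild-type 5, knockout 2 or knockout 4 the lens feature. Without knockout 1 or knockout 4 it called 2 Müller features, and without knockout 5 a second Trpm3 feature. fry gave an adjusted p of 7.91e-04 for the bipolar and the long non-coding RNA lists and of 1.33e-05 for the horizontal cell list, which camera did not call.

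With the replicate number as a block, over the 10 libraries numbered 1 to 5, limma called 3715 features higher and 3217 lower, 5916 of them shared. It also called MSTRG.8734 at Prdm1 (adjusted p = 0.00173), MSTRG.15161 at Aipl1 (adjusted p = 0.0148) and 1 vascular feature, each not called without the block. The deviations of same-numbered libraries correlated at 0.294, 0.00135, 0.123, 0.0512 and 0.273, and 1 of 5 wild-type libraries correlated best with its own number, so the numbers were not taken as pairing. Small changes could be missed: in the simulation limma recovered 2 of 70 changes of 1.5-fold, a recovery that was not split by depth. The simulation held a far smaller share of changed features than was called in the data, so this recovery may not hold here. For features with few reads, a count of 0 allows up to 4.11 normalised counts in wild-type 1.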

Other observations

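The features named near gene starts and the correlations of the second axis were chosen only after the result was seen.

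Intergenic features were also counted by the list of the gene with the nearest coding start, within 100 kb. Of 22 such features near glial and stress response genes 11 rose and the other 11 were not called. Among those that rose were 3 features near Fos and MSTRG.16977, with a log2 difference of 2.48. The middle of MSTRG.16977 lies 766 bp from the start of Stat3, a mediator of cytokine signalling. Near genes of horizontal cells 15 of 22 rose and 2 fell, the latter near Prox1. Of those that rose 13 lie near Lhx1, a homeobox gene of horizontal cells, with log2 differences of 1.28 to 2.69. They form a single run on the plus strand (chromosome 11, 84540275 to 84592365), so whether they are separate transcripts stays open. With the intergenic members counted in, camera gave an adjusted p of 4.11e-06 for the glial and 0.00666 for the horizontal cell list, and neither call held with an estimated correlation (adjusted p = 0.0657 for each). Near cone genes 10 of 20 features rose and 3 fell, near the transcription factor genes 13 of 27 rose and 5 fell, near bipolar genes 6 of 41 rose and 2 fell, near Müller glia genes 1 of 13 rose and near ganglion cell genes 2 of 11 rose. Some genes, such as Thrb, Otx2 and Onecut1, are on more than 1 of these lists, and their features are counted in each.

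Near Otx2, which lies within 10 Mb of Nrl, MSTRG.27960 went from 7.27 ± 5.17 (SD, n = 5) to 311 ± 57.4 (SD, n = 6), a log2 difference of 5.52. Near Atoh7, a proneural gene of ganglion cell precursors, the features MSTRG.9182 and MSTRG.9183 had log2 differences of 3.06 and 2.77. Near amacrine genes 5 of 17 features fell and the other 12 were not called; 3 of the 5 lie near the glycine transporter gene Slc6a9 and 2 near Prox1. Near the linker histone gene Hist1h1c, MSTRG.23435 (chromosome 13, 23730716 to 23733430) fell from 209 ± 44.3 to 8.18 ± 4.64, and MSTRG.23436 had a log2 difference of -2.50.

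A hypothesis for the intergenic features that changed was transcription running on from the end of a coding gene on the same strand, which would place them downstream of genes more often than uncalled ones. The reverse was found: 10.5% of 2937 called and 23.2% of 7860 uncalled intergenic features lay within 10 kb downstream, an odds ratio of 0.396 over 10 strata of abundance (95% interval over chromosomes 0.342 to 0.453). This argues against transcription running on as the source of most of them.

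The first principal component, which separated the groups, held 61.9% of the variance and the second 11.1%, which ordered libraries within both groups. A few features taking a varying share of the reads may lie behind the second: its Spearman correlation with the share of the 10 most abundant features was 0.645 (permutation p = 0.0375, adjusted p = 0.0749) and Pearson's r 0.632 (permutation p = 0.0356, adjusted p = 0.0712), over 11 libraries and 2 relations tested. Without the 2 libraries farthest from the median share r was 0.583, and within the 6 knockout libraries it was 0.682; 5 wild-type libraries are too few for a value. With total reads the Spearman correlation was -0.191 (permutation p = 0.575) and r -0.274 (permutation p = 0.413), and -0.517 without the 2 farthest libraries, so library size cannot be told apart with so few libraries. Feature length is argued against, since the correlation of loading and length across features, which are not independent, was 0.0155.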
